A study of Mus musculus with 2 samples.

How the data were processed

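Gene and transcript tables of 2 libraries of total RNA from mouse erythroid progenitor cells (CFU-Ery) were used, 1 gene table and 1 transcript table per library. The libraries were made from 1 ng of RNA with a fragment size range of 150 to 400 nt, per the labels, which also name the replicate numbers. The quantification was made per library on mm10 with GENCODE M4 from transcriptome alignments, per the deposited description of the files. The aligner, the quantification tool, their versions and the use of strand are not given in the sources used here, and replicates were not pooled.

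The deposited expected counts are estimated reads per gene or transcript that need not be whole, per the file headers. The deposited TPM values are scaled to a fixed total over all rows of a table, including mitochondrial rRNA and spike-ins, and the authors give both a maximum likelihood and a posterior mean value, per the file headers. The deposited FPKM values are scaled by length and by library size, per the file headers. The deposited isoform percent is the percent of a gene's TPM carried by a transcript, per the file headers. The deposited bounds of a credibility interval of TPM were treated as a score, since their level is not stated, and were not used in any result. TPM is dominated by a few mitochondrial genes here, so that a small change in their share moves every other gene's TPM; for this reason TPM was also rescaled so that nuclear protein-coding genes alone sum to the same total.

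Each gene table has 69691 entries, of which 43346 are Ensembl genes, 96 ERCC spike-ins, 1 a phiX control with 0 counts and 26248 are named only by a number. Gene names, types and coordinates (1-based) came from GENCODE M21 on GRCm38, the assembly also called mm10, by Ensembl identifier without version. Of the Ensembl genes, 42462 matched and 884 did not; 21461 were nuclear protein-coding. Entries that name no gene (0 and 8 counts, 0 and 7.23e-06% of counts) stayed out of gene tests. Of the listed genes, Ahsp and Snhg1 were not matched and have no value here.

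The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the 24 key genes, the 4 highest and 2 lowest members of each other list by mean TPM, the 10 most abundant nuclear protein-coding genes, the 5 most abundant lncRNA genes, the 5 genes furthest apart in each direction between the replicates (mean expected count of at least 100, mean TPM of at least 5) and the 5 listed genes with the most even split between transcripts. The text names those needed to describe each list; a few genes that the rule takes are not reported here. The lists cover erythroid transcription factors, red cell membrane and skeleton, haem synthesis and iron, adult and embryonic globins, late erythroid maturation, Epo signalling and survival, 8 other lineages, S phase, G2 and M phase, CDK inhibitors, D cyclins, replication-dependent histones, immediate early and stress genes, abundant non-coding RNA, Y-linked genes and mitochondrially encoded proteins.

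Genes were called detected at 1 TPM. Log values are log2(TPM + 1), which understates the difference of low genes. Erythroid genes were compared with each other lineage by the difference of mean log2(TPM + 1), averaged over the libraries, with a two-sided test of 100000 permutations of gene labels and Benjamini-Hochberg adjustment at 0.05. Cell cycle lists were placed among 10000 random lists of the same size. Stage genes were compared as log2 ratios of TPM with a 95% counting interval, and a gene at 0 was set at a floor of 3 counts per library. Between the replicates, log2 ratios were centred on their median over genes with a mean expected count of at least 20, which removed a shift of -0.05, and lists were placed among random lists matched on expression in 20 bins. Reads shared within pairs of near-identical genes were checked by the 25-mers both members hold and by whether fractional expected counts summed to a whole number. Expected counts were rounded to whole numbers for edgeR and DESeq2. The spread expected from sampling alone came from 100 binomial simulations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.

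The count of genes apart, the lineage test, the comparison of lists between replicates and the coefficient of variation were tested on simulated data. With 200 genes of a mean TPM of at least 5 changed 4-fold or 8-fold between the replicates, 100% were called over 2-fold apart at either size. Of the other genes 0 were called (9878 genes in all). These counts were drawn with counting error alone, without the spread seen between the libraries. Neither number therefore shows how the call performs at that spread. Recovery was not simulated for genes under 5 TPM, where adding 1 to TPM shrinks the log2 ratio. Of 200 simulated pairs of lists with no shift 4% fell under the threshold of the lineage test, and 100% with a log2 shift of 3. Of 200 lists with no shift 4.5% fell outside the central 95% in the comparison of replicates, and 100% with a log2 shift of 1. A simulated coefficient of variation of 40% was recovered as 40.15% (9492 genes).

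Alternatives were other minimums, pseudocounts, units and estimates, TMM, DESeq2 and spike-in scaling of expected counts, median-centred counts, other backgrounds, and leaving out each replicate in turn. For nuclear protein-coding genes the depth was 4717790 and 4093202 counts. Beyond counting error, genes averaging 20 to 100 counts varied by 55.2% between the libraries (biological coefficient of variation). Signal tracks and alignments were not used here.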

Results

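Total RNA was sequenced from erythroid progenitor cells, the dividing precursors of red blood cells, labelled CFU-Ery. They were primary cells of male C57BL/6J mice aged 5 to 6 weeks, and the labels name a bone marrow progenitor isolation. There was 1 group of 2 libraries, numbered biological replicates 1 and 2, each made from 1 ng of RNA with spike-in transcripts. The labels give both libraries the same donor record and separate biosamples, so they do not say whether the cells came from separate animals, and the spread between the libraries may be technical. The total expected count was 143491647 in replicate 1 and 110634458 in replicate 2, of which nuclear protein-coding genes held 4717790 and 4093202. The design holds no other group, so the questions addressed were which genes the cells expressed, how erythroid genes stood against genes of other lineages, and how closely the libraries matched. With 2 libraries an exact sign-flip test cannot go below p = 0.5, so levels are given as mean ± SD. The p-values below come from permuting gene labels between lists and describe these libraries.

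Mitochondrial RNA dominated the expected counts of both libraries. Reads outside the annotated entries are not in these shares, and their number is not known here because alignments were not used. The rRNA genes mt-Rnr1 and mt-Rnr2, which encode the structural RNAs of the mitochondrial ribosome, held 80.1% ± 1.57 (SD, n = 2) of all expected counts. The 13 mitochondrially encoded protein genes, all subunits of the respiratory chain and ATP synthase, held 9.18% ± 0.199 and had a median of 5104 ± 256 TPM. Gm42418 (ENSMUSG00000098178.1, chromosome 17, 39846958 to 39848788, GRCm38) held 4.95% ± 0.421; it is annotated as an lncRNA and is listed by RefSeq as a synonym of the rRNA-related pseudogene Rn18s-rs5. Nuclear protein-coding genes held 3.49% ± 0.291. Because the deposited TPM was scaled over every row, 1 TPM equals 43.1 TPM in replicate 1 and 37.0 TPM in replicate 2 when rescaled to nuclear protein-coding genes. Levels below are on the deposited scale unless called rescaled. Both scales are given for the detected genes, the lineage gaps and some of the lists.

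**Figure D1:**
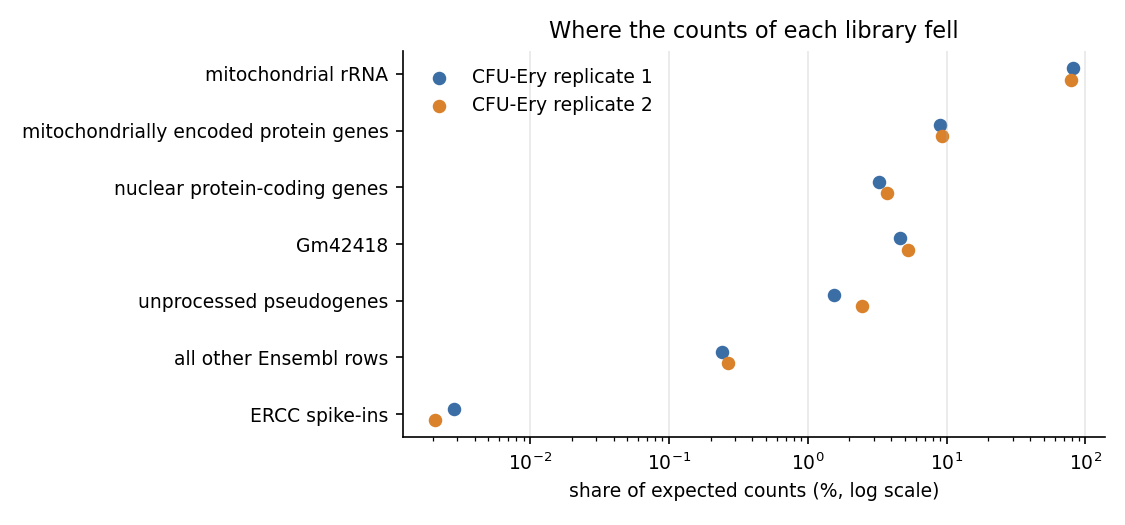
Share of expected counts by class of row (percent, log axis) in CFU-Ery replicate 1 (blue) and replicate 2 (orange), each point 1 library. Mitochondrial rRNA held 81.2% and 79.0%, and nuclear protein-coding genes 3.29% and 3.70%.

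Adult globin genes were the most abundant nuclear protein-coding genes. The beta globin genes Hbb-bs (ENSMUSG00000052305.5, chromosome 7, 103826534 to 103828096) and Hbb-bt stood at 2455 ± 237 and 1267 ± 211 TPM (SD, n = 2), and the alpha globin genes Hba-a2 and Hba-a1 at 2190 ± 394 and 1237 ± 163 TPM. These 4 genes held 28.4% ± 0.924 of nuclear protein-coding TPM. Some reads were divided between the members of each pair, because the members' expected counts were fractional and summed to a whole number (within 0.01 counts) in both libraries. Hba-a2 shared 93.6% of its 25-mers with Hba-a1, and Hbb-bt shared 60.2% with Hbb-bs; how many reads were divided was not measured. The embryonic globin genes Hba-x, Hbb-y and Hbb-bh1 had 0 counts in both libraries, and adult globins stood at least 128558-fold above a floor of 3 counts per library. The other 6 of the 10 most abundant nuclear protein-coding genes were S100a9, S100a8, the histone genes Hist1h4d and Hist1h1e, Cd24a, a surface glycoprotein of immature blood cells (160 ± 10.1 TPM), and Slc4a1. At a minimum of 1 TPM, 2961 genes were detected in both libraries (3285 in replicate 1 and 3532 in replicate 2), of which 2701 were nuclear protein-coding and 55 were lncRNA genes. On the rescaled TPM, 9572 nuclear protein-coding genes reached 1.

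The red cell membrane and skeleton genes were expressed without exception, with 17 of 17 at or above 1 TPM in both libraries and a median of 18.6 ± 1.18 TPM (741 ± 33.3 rescaled). Slc4a1 (ENSMUSG00000006574.11, chromosome 11, 102348824 to 102366203), the band 3 anion exchanger, led at 136 ± 17.5 TPM (5421 rescaled), ahead of the blood group gene Kel at 76.3 ± 8.17. Of the haem synthesis and iron genes, 18 of 22 reached 1 TPM (median 15.03 ± 1.67), led by Alas2 (ENSMUSG00000025270.9, chromosome X, 150547375 to 150570638), the erythroid enzyme of the rate-limiting step of haem synthesis, at 69.9 ± 11.2 TPM. The ferritin gene Fth1 followed at 69.0 ± 13.0, the mitochondrial iron importer gene Slc25a37 at 64.9 ± 0.339 and the transferrin receptor gene Tfrc at 59.0 ± 0.856, while Ireb2 and the haem exporter gene Flvcr1 were lowest at 0.625 ± 0.163 and 0.165 ± 0.00707. Of the erythroid transcription factor genes, 12 of 17 reached 1 TPM (median 3.26 ± 0.212). Lmo2 stood at 16.6 ± 2.12 TPM, E2f4 at 11.8 ± 1.08, Nfe2 at 10.3 ± 0.191, Klf1 at 7.64 ± 1.93, Tal1 at 6.24 ± 1.17 and Gata1 (ENSMUSG00000031162.10, chromosome X, 7959260 to 7978071), the master regulator of the lineage, at 5.81 ± 0.184. Myb stood at 2.54 ± 0.191 and Bcl11a, a repressor of embryonic globins, at 0.570 ± 0.0141. Late erythroid maturation genes reached 1 TPM in 14 of 15 cases (median 6.20 ± 0.757), led by the carbonic anhydrase gene Car2 at 65.8 ± 1.70, Prdx2 at 62.3 ± 14.8 and Hemgn at 37.1 ± 2.52. Of the Epo signalling and survival genes, 5 of 21 reached 1 TPM (median 0.12 in each library): the erythropoietin receptor gene Epor stood at 6.12 ± 0.757, Mcl1 at 4.67 ± 0.403, the survival gene Bcl2l1 at 2.37 ± 0.615 and Jak2 at 1.99 ± 0.170, and Socs2 and Trib3 had 0 counts. Stat5a and Stat5b, at 0.135 ± 0.0636 and 0.210 ± 0.0990 TPM, share reads as close paralogs.

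Erythroid genes stood above the genes of 7 of the 8 other lineages examined. The 56 erythroid genes (transcription factors, membrane and skeleton, haem and iron) had a mean log2(TPM + 1) of 3.42, which was 3.13 ± 0.09 (SD, n = 2) above stem and multipotent progenitor genes, 3.15 ± 0.05 above megakaryocyte genes, 3.00 ± 0.08 above T and NK lymphoid genes and 3.27 ± 0.10 above stromal and endothelial genes. The gap was smaller to B lymphoid genes (2.37 ± 0.12), to eosinophil, basophil and mast cell genes (2.55 ± 0.04) and to macrophage genes (2.24 ± 0.03). On the rescaled TPM all 7 gaps were larger, at 6.01 for stem, 6.13 for megakaryocyte, 5.07 for T and NK and 6.83 for stromal genes. They were 3.23 for B lymphoid, 4.32 for eosinophil, basophil and mast cell and 3.23 for macrophage genes. The granulocyte and monocyte genes were the exception, with a mean log2(TPM + 1) of 3.29, a gap of 0.13 ± 0.03 (0.36 on the rescaled TPM). The highest of them were S100a9 (ENSMUSG00000056071.8, chromosome 3, 90692632 to 90695721) at 211 ± 54.3 TPM and S100a8 at 204 ± 46.9 TPM, which encode the calprotectin subunits of neutrophils, Ngp at 97.1 ± 16.5 and the lysozyme gene Lyz2 at 46.3 ± 9.69. The myeloperoxidase gene Mpo, a key gene, stood at 26.7 ± 0.778. The myeloid transcription factor genes were lower: Spi1 stood at 1.19 ± 0.191, Irf8 at 0.390 ± 0.0849 and Cebpa at 0.18 in each library. All 18 granulocyte and monocyte genes had at least 10 counts in both libraries, 12 reached 1 TPM, and together they held 2.69% ± 0.270 of nuclear protein-coding TPM.

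By two-sided permutation of gene labels, Benjamini-Hochberg adjusted over 8 lists, adjusted p was 2.0e-05 for the stem, megakaryocyte, T and NK and stromal lists, where the unadjusted p of 1e-05 was the smallest the permutations can give. It was 5.7e-05 for the B lymphoid, the macrophage and the eosinophil, basophil and mast cell lists, and 0.812 (unadjusted 0.812) for the granulocyte and monocyte list. The erythroid mean was higher in both libraries against every list. With members under 1 TPM left out, the granulocyte and monocyte genes stood above the erythroid genes, at a difference of -0.52; without S100a8, S100a9, Ngp and Lyz2, an alternative chosen after seeing the data that removes the 4 highest members, the erythroid genes stood 1.16 above (adjusted p = 0.0357 by permutation).

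**Figure D2:**
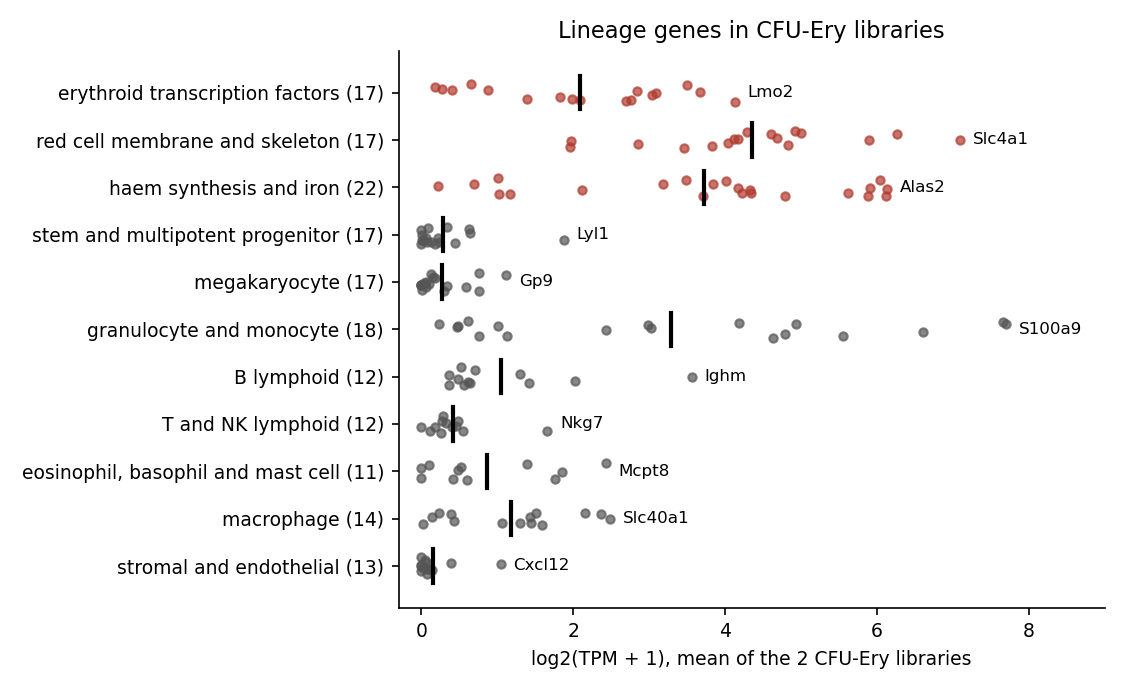
Mean log2(TPM + 1) of each gene over the 2 CFU-Ery libraries, by list (number of genes in brackets), erythroid lists in red and other lineages in grey; the black bar is the list mean and the highest gene is named. The granulocyte and monocyte list, with a mean of 3.29, overlaps the erythroid lists, and the stromal and endothelial list has the lowest mean (0.15).

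On the deposited TPM the other lineage lists had few members at 1 or more, except the macrophage list. The stem and multipotent progenitor genes had 1 of 17 members at 1 TPM or more, Lyl1 at 2.67 ± 0.0919, with Cd34 at 0.165 ± 0.106 and Gata2 at 0.270 ± 0.170. No megakaryocyte gene of 17 reached 1 TPM in both libraries; Gp9 stood at 1.20 ± 0.474 and the platelet factor gene Pf4 at 0.755 ± 0.643. The B lymphoid list had 4 of 12 members at 1 TPM or more, led by the immunoglobulin heavy chain gene Ighm (10.9 ± 1.58) and Cd79b (3.06 in each library). The T and NK lymphoid list had 1 of 12, Nkg7 at 2.16 ± 0.0707. The eosinophil, basophil and mast cell list had 4 of 11, led by the basophil protease genes Mcpt8 (4.39 ± 0.297) and Prss34 (2.61 ± 0.396). The macrophage list had 9 of 14, led by the iron exporter gene Slc40a1 (4.61 ± 0.212), the complement gene C1qb (4.18 ± 0.658) and Vcam1 (3.51 ± 0.856). No stromal and endothelial gene of 13 reached 1 TPM in both libraries, and Cxcl12 was highest at 1.08 ± 0.354. On the rescaled TPM more members reached 1 in both libraries. These were 12 of 12 B lymphoid, 10 of 12 T and NK lymphoid and 13 of 14 macrophage genes. The stem list had 11 of 17, the megakaryocyte list 9 of 17 and the stromal and endothelial list 7 of 13. The eosinophil, basophil and mast cell list had 8 of 11.

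Genes of the G2 and M phases of the cell cycle were abundant. All 17 reached 1 TPM, with a median of 8.57 ± 0.728 TPM (SD, n = 2), led by the proliferation marker Mki67 at 99.0 ± 11.5 TPM, the topoisomerase gene Top2a at 29.5 ± 1.72, Birc5 at 22.0 ± 0.438 and the cyclin gene Ccna2 at 19.6 ± 1.40. All 15 S phase genes also reached 1 TPM (median 4.11 ± 0.827), led by the replication clamp gene Pcna at 24.3 ± 0.651 and the ribonucleotide reductase gene Rrm2 at 17.1 ± 1.11. Of 21 replication-dependent histone genes, 20 reached 1 TPM (median 16.6 ± 0.665), led by Hist1h4d at 182 ± 48.6 and the linker histone gene Hist1h1e at 113 ± 26.8; near-identical histone copies can share reads. Of the 7 CDK inhibitor genes, 3 reached 1 TPM, Cdkn2d (9.01 ± 1.20), Cdkn2c (5.25 ± 0.0354) and Cdkn1b (1.95 ± 0.297), while Cdkn2a and Cdkn2b had 0 counts. Among the 3 D cyclin genes, Ccnd3 stood at 9.34 ± 1.09 TPM, Ccnd2 at 0.315 ± 0.0212 and Ccnd1 at 0.05 ± 0.0141. Among 10000 random lists drawn from the 2961 detected genes, the G2 and M phase median lay at percentile 99.97, outside the central 95%, and the S phase median at 92.0, inside it; the histone list was not placed among random lists. The CDK inhibitor and D cyclin medians lay under the 1 TPM minimum of that background, so their percentile in it carries no information. Against protein-coding genes with a count in both libraries, the S phase median lay at percentile 100 and the D cyclin median at 39.4. The CDK inhibitor list cannot be placed there either, because its median gene Cdkn1c, with 0 counts in replicate 1, lies outside that background, as do Cdkn2a and Cdkn2b.

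Genes of erythroid commitment exceeded their earlier or alternative counterparts. Gata1 exceeded Gata2, which it replaces as erythroid cells mature, by 4.59 ± 1.02 on the log2 scale (SD, n = 2). The replicates stood apart, at 5.31 (95% counting interval 4.94 to 5.70) and 3.86 (3.60 to 4.14). Gata1 exceeded the myeloid factor gene Spi1 by 2.30 ± 0.19, Alas2 exceeded the housekeeping gene Alas1 by 6.08 ± 0.16, and Ccnd3 exceeded Ccnd2 by 4.89 ± 0.27. The stem cell factor receptor gene Kit (ENSMUSG00000005672.8, chromosome 5, 75574916 to 75656722) stood at 0.395 ± 0.0495 TPM, with 196 and 190 counts, and its log2 ratio to Slc4a1 was -8.43 ± 0.37. In expected counts, without length scaling, Gata1 to Gata2 was 3.84, Alas2 to Alas1 was 4.81 and Ccnd3 to Ccnd2 was 3.34. All intervals and floors cover counting error alone, because PCR copies of 1 molecule are not independent.

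Among the 14 listed non-coding RNA genes, small structural RNAs were the highest. The signal recognition particle RNA genes Rn7s1 and Rn7s2 stood at 1609 ± 173 and 1609 ± 173 TPM. Their counts were near equal, at 32344 and 32343 in replicate 1 and 28831 and 28825 in replicate 2, as an even split of shared reads would give. Their levels are therefore best not read as separate, although shared 25-mers were not checked for this pair. Rn7sk, which restrains transcription elongation, stood at 842 ± 87.0 and the RNase P RNA gene Rpph1 at 732 ± 110.5, and 7 of the 14 reached 1 TPM (median 10.3 ± 1.80). The most abundant lncRNA genes after Gm42418 were Malat1 at 279 ± 20.1, Gm26917 at 130 ± 10.3, Gm42743 at 120 ± 18.9 and the snoRNA host gene Gas5 at 18.99 ± 2.74. These are lncRNA genes by annotation. Names related to rRNA were looked up for Gm42418 only, so rRNA reads at the others, such as Gm26917, were not checked. Of 13 immediate early and stress genes, 2 reached 1 TPM (median 0.240 ± 0.0707), Dusp1 at 3.49 ± 0.269 and Zfp36 at 1.64 ± 0.389. The 4 Y-linked genes had a median of 0.893 ± 0.00354 TPM, with Eif2s3y at 3.13 ± 0.502. Xist, transcribed from the inactive X chromosome of females, had 25 counts in replicate 1 and 0 in replicate 2.

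The replicates matched most closely for abundant genes. Of 9878 genes with a mean expected count of at least 20, 62 were over 2-fold apart on the median-centred log2(TPM + 1) scale, 25 higher in replicate 1 and 37 higher in replicate 2. Binomial sampling alone gave a mean of 2.67 such genes. Both numbers are limited by the scale, on which a gene under 1 TPM in both libraries can hardly pass 2-fold. Only 3856 genes reached 1 TPM in either library, so most of the 9878 could hardly be called apart. The mitochondrial ATP synthase gene mt-Atp6 was higher in replicate 1 by a log2 ratio of 1.03 (19812 against 10024 TPM), and the pseudogene Gm10925 (ENSMUSG00000100862.1, chromosome 1, 24613974 to 24614651) was higher in replicate 2, with a log2 ratio of -3.31 (1308 against 13411 TPM). Among genes averaging at least 100 counts and 5 TPM, the next towards replicate 1 were Nrd1 (0.79), Ptp4a2 (0.78), Ggnbp2 (0.68) and Atp2b4 (0.68), all under 2-fold. Towards replicate 2 the pseudogenes Rpl37rt (-1.06) and Gm15387 (-1.06) were over 2-fold apart and the pseudogene Gm10177 (-0.94) was not, and all 3 can share reads with their parent genes. This compares 2 libraries of the same group, not conditions. On log2(expected count + 1), 1799 genes were over 2-fold apart with median centring alone, a unit tried after seeing the data, and 1798 with edgeR's TMM. On log2(TPM + 0.1) 1023 were, against a mean of 236 from binomial sampling.

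Across 3856 genes at or above 1 TPM in either library, Pearson's r of log2(TPM + 1) was 0.952 and Spearman's rho was 0.835; genes are not independent replicates, so no p is given. The biological coefficient of variation from edgeR was 37.2% over all 9882 genes fitted, 55.2% for genes averaging 20 to 100 counts, 23.9% for 100 to 1000 counts and 11.9% above 1000 counts. A level of a gene such as Slc4a1, with 72125 and 67646 counts, is therefore better determined than that of Pf4, with 18 and 56. The 96 spike-in transcripts, of which 18 had counts in both libraries, correlated at r = 0.949 across transcripts and took 4084 and 2291 counts. Per nuclear protein-coding count, spike-ins were 1.55 times as abundant in replicate 1 as in replicate 2.

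**Figure D3:**
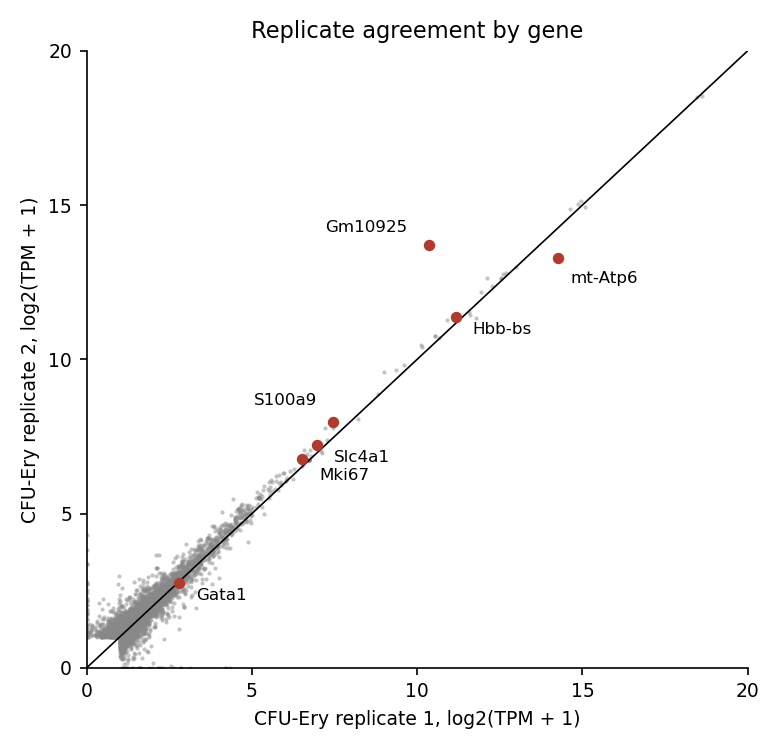
Each grey point is 1 gene at or above 1 TPM in either library (3856 genes), by log2(TPM + 1) in CFU-Ery replicate 1 (x axis) and replicate 2 (y axis); the line marks equal values and named genes are red. Most genes lie along the line (Pearson's r = 0.952), and Gm10925 and mt-Atp6 lie off it on opposite sides.

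Of the gene lists, 23 had at least 3 members to compare between the replicates, and 2 had a median outside the central 95% of 10000 random lists matched on expression, where 1.15 would be so by chance. The mitochondrially encoded protein genes had a median centred log2 ratio, replicate 1 over replicate 2, of 0.02 (percentile 97.9), and the Epo signalling and survival genes, of which 12 were compared, of -0.15 (percentile 2.30). The first median turned to -0.49 with spike-in scaling and to -0.026 with no centring, where the median of all genes moved by -0.62 and -0.05, and the list's percentile stayed between 97.9 and 99.9 in each setting. Several of the mitochondrial genes share sequence with nuclear copies, and this list was not placed with each gene summed over its copies. Matching on expression was also coarse for the mitochondrial list, because few other genes lie at its level. Its members averaged 461 TPM (mt-Nd3) or more. Of nuclear protein-coding genes only the adult globins did so, followed by S100a9 at 211 TPM. The place of the mitochondrial list outside the central 95% therefore cannot be read as a shift. In expected counts centred on their median, a unit tried after seeing the data, the Epo list lay inside that range (percentile 26.4), as it did in TPM with a pseudocount of 0.1 (5.88) or with the mean of its genes (11.8). The erythroid transcription factor (percentile 51.0), red cell membrane (64.5), haem and iron (33.3) and granulocyte and monocyte (24.5) medians lay within it. These lists therefore did not stand out from genes matched on expression. Shifts smaller than the simulated log2 shift of 1 may have gone unseen.

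The leading transcript of a gene was mostly shared by the replicates. Of 199 genes at or above 10 TPM with several annotated transcripts, 183 (92.0%) had the same most abundant transcript in both libraries, and its median share of the gene was 71.7% ± 2.33 (SD, n = 2). In 54 genes the leader held at least 90% in both libraries, and in 36 it held under 50%. Slc4a1 was near-complete in 1 transcript of 4545 nt (99.9% ± 0.0707), whereas the leading Tfrc transcript held 47.0% ± 2.30 and the leading Alas2 transcript, 569 nt long, 58.6% ± 2.25. These are shares of TPM, which is scaled by length. In expected counts the leading Alas2 transcript held 2022 of 7453 in replicate 1 and 2080 of 6835 in replicate 2. The skeletal protein genes Epb41 and Ank1, with 18 and 17 annotated transcripts, had the most even splits among the listed genes, with leaders at 23.5% ± 1.45 and 26.2% ± 1.52, followed by Malat1, Gas5 and Top2a. The Ank1 leader, 1740 nt long, had 1608 and 1292 counts, against 5127 and 4935 for the second transcript of 8201 nt. For Malat1 and Gas5 the leader changed between libraries. In Malat1 a 656-nt transcript held 29.1% in replicate 1 and 18.8% in replicate 2, and a 485-nt transcript 25.6% and 30.7%, on 2654 to 5865 counts per transcript and library. Malat1 had 55725 and 42278 counts in all, so most of its counts lay on other transcripts. In Gas5 a 403-nt transcript held 31.6% and 13.5%, and a 502-nt transcript 19.2% and 34.7%, on 77.0 to 272 counts, of 1206 and 1115 for the gene.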

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

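The tests of mt-Atp6 with Gm10925 and of Kit with Slc4a1 were chosen after their results were seen, and those of the granulocyte genes before. The design has 1 group, so no biological difference between groups was tested.

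Signal appeared in entries outside the comparisons, above the 3 counts that an empty entry allows. Entries named only by a number held 8 counts in replicate 2. Ensembl genes with no matching name held 16854 counts in replicate 1 and 14145 in replicate 2.

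mt-Atp6 was higher in replicate 1 (log2 ratio 1.03) while Gm10925 was higher in replicate 2 (-3.31). More mt-Atp6 RNA in replicate 1 is argued against by mt-Atp8, which overlaps it in the same transcript and had a log2 ratio of 0.21. All 654 of the 25-mers of Gm10925 occur in mt-Atp6, and the summed TPM of both genes had a log2 ratio of -0.10, so reads shared between a mitochondrial gene and its nuclear copy may account for the opposite shifts. mt-Co3 (0.49) and its copy Gm28437 (-0.45) also moved oppositely, with a sum at -0.11. TPM of these genes is best read as the sum over copies.

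Granulocyte and monocyte genes stood near the erythroid level. Reads shared with other abundant genes are argued against: the median gene of the list shared 0% of its 25-mers with other genes at or above 1 TPM, and the highest, Ly6c2, 3.47%. A list of 18 further granulocyte genes, of which only Lcn2 had been looked at, had a median of 83.2 rescaled TPM. This lay at percentile 99.96 of random lists of protein-coding genes with a count in both libraries. Lcn2 stood at 33.7 ± 6.17, Chil3 at 13.9 ± 2.25 and Retnlg at 12.8 ± 1.61 TPM (SD, n = 2). Granulocyte-lineage cells, or RNA released from them, may therefore be in the samples; 2 members of the fixed list, Mpo and Spi1, are also key genes, and the progenitor isolation's gates are not given in the sources used here. The check does not single out granulocytes, because no other lineage list was placed in that background. The macrophage list had a median of 62.8 ± 3.00 rescaled TPM and the B lymphoid list 21.8 ± 1.80. Whether cells or free RNA carried the granulocyte transcripts stays open.

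Kit stood far below Slc4a1. The length scaling of TPM is argued against, since the log2 ratio was -8.50 in unscaled counts and -8.43 in TPM. RNA mainly from cells later than the labelled stage cannot be told apart from the labelled stage, as no profile of staged cells was used; 14 of 15 late erythroid maturation genes reached 1 TPM in both libraries, which that explanation needs and an earlier stage with some maturing cells could also give.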

How the results depend on the processing

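Of 297 alternative values, 261 changed little: tested values kept their side of the threshold, counts stayed within 1.5 times, correlations within 0.05 and other values within 1 SD. For the stage gene ratios, leaving out 1 of 2 libraries stays within 1 SD by construction, so those values carry no information on stability. Among the 261, 19 medians of lists inside the central 95% between the replicates stayed inside with the other sign, 6 of them with the spike-in sum. The median of the mitochondrially encoded protein genes, outside that range, turned from 0.02 to -0.49 with the spike-in sum. It turned to -0.026 with no centring. These turns followed the shift of all genes (-0.62 and -0.05), while the list's percentile stayed at 99.1 and 97.9. Few other genes lie at the level of this list, so its percentile rests on coarse matching. The cause of the other changes was not tested unless the setting itself gives it. The alternatives on mitochondrial copies, on the granulocyte list and on median-centred counts were chosen after seeing the data. No paired analysis was possible because there was 1 group. The erythroid excess over 7 lineages held under each setting that gave a value, with adjusted p between 1.6e-05 and 0.0317 (permutation); leaving out members under 1 TPM gave no value for the stem, T and NK and stromal lists, with fewer than 2 members left. The gap to granulocyte and monocyte genes turned to -0.52 with those members left out, and was 1.16 without S100a8, S100a9, Ngp and Lyz2, where the 4 highest genes are removed by construction; over the planned settings its adjusted p ranged from 0.328 to 0.842. Genes detected numbered 4624 at 0.5 TPM, 678 at 5 TPM and 10868 on the rescaled TPM. Against protein-coding genes with a count in both libraries, the S phase percentile was 100 and that of D cyclins 39.4, where the reported background leaves out genes under 1 TPM by construction. In expected counts Gata1 to Spi1 was 2.74, Alas2 to Alas1 4.81 and Ccnd3 to Ccnd2 3.34, and Kit to Slc4a1 was -8.06 with posterior mean TPM. Gata1 to Gata2 was 3.86 without replicate 1 and 5.31 without replicate 2.

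Pearson's r was 0.875 with a pseudocount of 0.1, 0.896 for spike-ins in counts, and the median share of the leading transcript 65.5% at 1 TPM and 74.2% at 50 TPM. Genes over 2-fold apart numbered 1799 (51.5% higher in replicate 1) on log2(expected count + 1) with median centring alone. The rise from 62 therefore needed no other scaling. The change from TPM to counts also made the pseudocount of 1 smaller against the values, so the rise cannot be put down to the unit alone. On log2(expected count + 1) such genes numbered 1798 with TMM (52.0%), 1799 with DESeq2 (51.9%) and 2841 with the spike-in sum (14.0%). In TPM they numbered 1023 with a pseudocount of 0.1, 23 at 100 counts or more, 139 with no filter, 63 with no centring (28.6%, against 40.3% as reported) and 60 without mitochondrial genes and their copies. Lists apart numbered 1 on median-centred, TMM, DESeq2 or spike-in scaled counts, and 1 in TPM with a pseudocount of 0.1 or the mean. Low genes varied most: 35.0% of genes averaging 20 to 100 counts were over 2-fold apart on TMM-scaled counts, and 0.221% above 1000 counts. At a pseudocount of 0.1, sampling at this depth alone gave a mean of 236 genes against the 1023 found, and the cause of the excess was not tested.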

Other observations

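The groups and genes here were chosen after their values were seen, so no test of them is given. The 80 ribosomal protein genes matched by symbol had a median of 689 ± 53.4 rescaled TPM (SD, n = 2) and held 5.67% ± 0.297 of nuclear protein-coding TPM; several have processed pseudogenes that can share reads. All 8 condensin genes, which compact chromosomes for mitosis, reached 1 rescaled TPM, with a median of 225 ± 0.818, led by Ncapd2 at 25.4 ± 3.90 and Smc4 at 22.6 ± 2.08 TPM. Ube2c, which serves the anaphase-promoting complex, stood at 31.4 ± 5.11.

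Among single genes outside the lists, the elongation factor gene Eef1a1 stood at 112 ± 5.44 TPM, the glutathione peroxidase gene Gpx1 at 111 ± 14.9, the protease gene Ctse at 101 ± 10.8, the mitochondrial leucyl-tRNA synthetase gene Lars2 at 90.7 ± 1.42 and Tpt1 at 81.3 ± 8.11. The immunoglobulin light chain gene Igkc stood at 28.9 ± 2.62 TPM, above Ighm at 10.9 ± 1.58. The nuclear copies of mitochondrial genes with a mean of at least 1 TPM numbered 9, of which 7 lie between 24611535 and 24616197 on chromosome 1. The highest, Gm29216, stood at 25367 and 30160 TPM beside its parent mt-Co1 at 31625 and 36061.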
